A study of Mus musculus with 20 samples.

How the data were processed

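RNA from 2 pools was measured on Mergen ExpressChip MO3 one-colour oligonucleotide arrays: a pool of adult C57/B6 mouse retina and a pool of cortex from Swiss-Webster mice at postnatal day 1. Per the labels, 20 µg of DNase-treated total RNA was reverse-transcribed from a T7 promoter primer, and the second-strand product was transcribed in vitro with a biotin-tagged nucleotide. Each pool was hybridised to 5 arrays at each of 2 sites, which gives 4 groups and 20 arrays. The labels mark 1 of the sites as site 2, and the arrays without that mark are called the first site here. The labels describe the 5 arrays of a group as technical replicates of 1 pool. Every p-value for a difference between groups therefore measures the spread between arrays and not between animals. Permutation tests over rows or copy numbers take rows as the unit. Tissue differs together with strain and age, and each comparison of retina with cortex is therefore a comparison of these 2 pools.

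The deposited values are intensities on a linear scale, 1 value per row and array in a single table, with 0 as the lowest value. They are recorded as background-corrected intensities, but the scanner, the method of that correction and any scaling by the authors are not given in the sources used here. The medians of the deposited intensities differed between arrays, from 35.3 to 259 units, so the table was not already normalized between arrays. The table held 9248 rows. Its row identifiers were paired with gene symbols through the platform annotation, updated through Entrez identifiers with the RefSeq gene table of assembly GRCm38.p6. There were 7897 rows with 1 symbol, 12 with several and 1339 without a listed gene, and 7856 of the rows with 1 symbol matched the gene table. No genome coordinates are printed.

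In general the row names did not match the values, as the checks in the results show. The 32 copies listed under each of 11 repeated control names spread as widely as random rows. The levels of copy 32 of 2 control series did follow their listed names, so some names may be right, but which ones is not known. A name therefore serves here only as the label of a row, written as the row "listed as" or "listed under" a gene, and no level or difference is attributed to the gene itself. Because the true places of the controls are not known, all rows stayed in the tests. Reordering the rows was not attempted for any reported value, since the array's layout was not used here.

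The intensities of all 20 arrays were quantile normalized, values under the 5th percentile of the positive normalized values (2.86 intensity units, 1.52 on the log2 scale) were set to that floor, and log2 was taken. One linear model with the 4 groups was fitted to all 9248 rows with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). Contrasts gave retina against cortex at the first site, at site 2 and as the mean of both, the difference between the 2 tissue differences (the tissue by site interaction), and site 2 against the first site within each pool. A row was called when its Benjamini-Hochberg adjusted p over all rows was under 0.05 and its log2 difference was at least 1 in size. On simulated data with 200 changed rows among 9248, the contrast over both sites recovered 79.1% of rows changed by 1.5, 97.0% of rows changed by 2 and 100% of rows changed by 3 on the log2 scale, with 3 false calls. The interaction recovered 55.2%, 67.2% and 87.9%, with 4 false calls. Each simulated row had the same SD in all 4 groups and independent values between arrays, without a floor or normalization. These shares and false calls are therefore not error rates of the real data. The comparison of copies was tested on simulated control rows too, where the spread within a correct name was set much smaller than that of all rows. There the median ratio of the SD within a name to the SD of all rows was 0.0976 for correct names and 0.908 for shuffled ones. The first value follows from that setting and does not show what correctly named copies on these arrays would give.

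The rule for named rows, the gene lists and the first set of other settings were fixed before the data were examined. For the contrast over both sites the rule takes the 15 largest and the 15 smallest log2 differences among rows with 1 symbol that were called at each site in the same direction, without overlap of the retina and cortex arrays at either site and with the brighter tissue above the median row. For the interaction and the site comparisons it takes the 5 largest called differences in each direction among rows with 1 symbol and the brighter group above the median row. The brightest row stood for a gene with several rows. For the gene lists the rule takes up to 4 called members each and all housekeeping controls. Given the mismatch of names, members are printed only for some lists, which were chosen after the values were seen. The 29 lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, over 7773 genes. On simulated data camera found the 1 list that had been shifted and no other. In that simulation rows varied independently, and no row outside the list differed between the tissues. It therefore does not show what camera could find among the wide differences of the real rows.

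Other normalizations, floors, filters, thresholds, array weights, a block for the replicate number and the omission of each array in turn were tried as alternatives. There were 3 first-site arrays with over 700 rows at 0. Treating them as a block, leaving them out and leaving out the rows listed as controls were added after the data were seen; the labels name no batch, so whether these arrays form one is not known. Precision is limited by the number of arrays. Values between 5.15% and 8.77% of rows lay at the floor on each array. No 2 arrays held identical values, and the smallest median difference between any 2 arrays was 0.19 on the log2 scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.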

Results

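The series measured 2 mouse RNA pools repeatedly on 1 array platform, with 5 replicate arrays per pool and site, to assess the variation within the platform and, with the arrays marked site 2, between sites. The retina pool came from adult C57/B6 mice and the cortex pool from Swiss-Webster mice at postnatal day 1. The 4 groups were retina and cortex at the first site and retina and cortex at site 2. The median deposited intensity was 204 ± 36.0 units (SD, n = 5) for retina and 201 ± 8.88 for cortex at the first site, and 55.8 ± 16.8 and 107 ± 34.9 at site 2. Retina and cortex arrays were both dimmer at site 2 (two-sided exact permutation test, p = 0.00794 for each pool, the smallest possible p, and 0.0476 after Benjamini-Hochberg adjustment over 12 comparisons). Retina was dimmer than cortex at site 2 with an exact permutation p of 0.0317, or 0.0952 after adjustment.

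**Figure D1:**
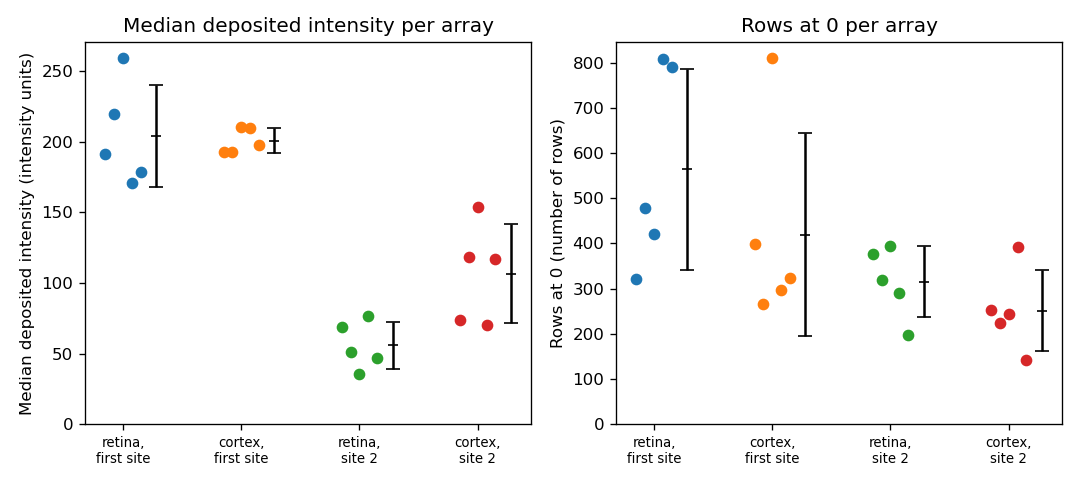
Median deposited intensity (left, intensity units) and number of rows at 0 (right) for each of the 20 arrays by group; points are arrays, and the bar beside them is the mean with its SD (n = 5). Every site 2 array had a median of 154 units or less, and 3 first-site arrays had between 791 and 811 rows at 0.

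Replicate arrays of a group correlated across rows with r between 0.965 and 0.988 for retina and between 0.960 and 0.984 for cortex at the first site, and between 0.939 and 0.963 and between 0.937 and 0.972 at site 2 (rows are not independent replicates). The median SD of a row between the 5 arrays was 0.31 for retina and 0.29 for cortex at the first site and 0.34 and 0.32 at site 2 on the log2 scale. In the quartile of rows with the lowest levels, that SD was 0.48 and 0.63 at the first site but 1.07 and 1.06 at site 2, while in the brightest quartile it was between 0.18 and 0.23 in all 4 groups. For the median absolute deviation of an array from the rest of its group, no difference between the sites was shown. The two-sided exact permutation p was 0.532 for retina and 0.421 for cortex, and 0.638 and 0.631 after adjustment over 12 comparisons. This median over all rows does not describe the dim rows, whose SD was larger at site 2. Arrays of the same pool at different sites correlated with a mean r of 0.935 for retina and 0.944 for cortex, above the 0.901 and 0.878 between the tissues within a site. At the first site, 2 retina arrays and 1 cortex array had 791 to 811 rows at 0 against 267 to 479 on the other 7 arrays.

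Several groups of rows with known relations were compared to check the row names, and these checks were chosen after the results were seen. The table lists 11 repeated controls with 32 copies each, and the lowest copy of each name lay at 1.55 to 1.74 on the log2 scale and the highest at 12.08 to 14.34: the median SD of the copies was 1.14 times the SD of all rows, while 1000 random groupings gave at least 0.859. The 114 pairs of rows listed under the same gene had a correlation of 0.0578 in the tissue difference (permutation p = 0.25) and of 0.0828 in level (permutation p = 0.18). The 42 rows listed under cytosolic ribosomal proteins, abundant in nearly all cells, lay at the centre of all levels, with a probability of 0.504 of exceeding a random row (permutation p = 0.94). The 29 rows listed under rod photoreceptor genes, which encode the light-sensing machinery of the retina, exceeded a random row in the tissue difference with a probability of 0.543 (permutation p = 0.41, and 0.82 after adjustment over 6 tests). The values themselves were reproducible, with row means of the same pool correlating between sites at 0.962 for retina and 0.971 for cortex. The names below are therefore labels of rows, and the values are not attributed to the genes.

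**Figure D2:**
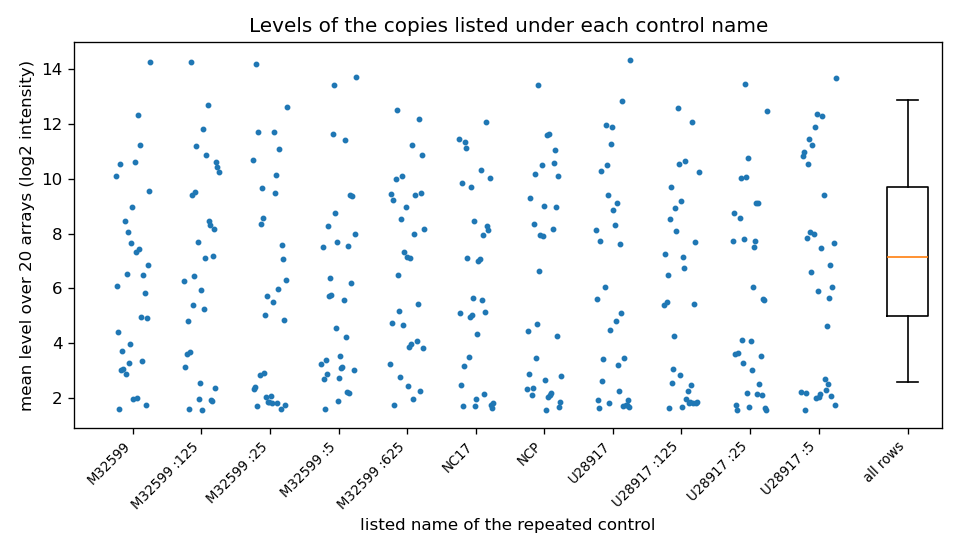
Mean level over 20 arrays (log2 intensity) of each of the 32 copies listed under 11 repeated control names; the box on the right shows the quartiles of all 9248 rows, with whiskers from the 5th to the 95th percentile. Lowest copies lie at 1.55 to 1.74 and highest copies at 12.08 to 14.34, with a median SD of 1.14 times that of all rows.

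Retina and cortex differed in 26.1% of the rows over both sites. The largest difference over both sites was in the row listed as Tnni1, 9.95 ± 0.16 (SE) higher in retina on the log2 scale, with an adjusted p of 2.38e-19; its means were 14.91 in retina and 4.26 in cortex at the first site, and 14.40 and 5.15 at site 2. Rows listed as Acrv1, Gabpb1, Efnb2, Tfpi2 and Spop followed with differences of 9.45, 9.37, 9.36, 9.25 and 9.01. Next came the row listed as Snx4, with a difference between those of Spop and Nolc1, and rows listed as Nolc1, Pcp2, Ntrk2 and Tra2b, higher in retina by 8.83, 8.70, 8.67 and 8.67. Those listed as Traf2, Oas3, Dnase1 and Tfrc were higher by 8.57, 8.29, 8.27 and 8.13. In the other direction the row listed as Anapc11 fell by 7.51 ± 0.14 (SE), from 12.81 in cortex to 5.54 in retina at the first site and from 12.65 to 4.90 at site 2. Differences in the rows listed as Klc1, Clock, Brca1, Rps20 and Cxcl9, all lower in retina, were -7.46, -7.05, -7.01, -6.92 and -6.51. Those listed as Dcx, Pcdhb15, Anxa8, Mthfs and Ubtf had differences of -6.31, -6.29, -6.24, -6.09 and -5.92. Those listed as Cdh23, Mta2 and Srm had differences of -5.57, -5.47 and -5.34. On all 5 retina arrays of the first site the row listed as Ngly1 was at the floor, so its difference of -5.32 depends on that floor and shrank to -2.55 with the higher one (4.76 on the log2 scale). Of the 30 rows, 14 had a group mean under the higher floor, and with it 7 differences shrank by over 1, all still called. Besides Ngly1, these were the rows listed as Clock (-5.60), Brca1 (-5.11), Mthfs (-4.88), Mta2 (-4.34), Srm (-3.88) and Snx4 (7.86), so their sizes and ranks are uncertain. The rows listed as Oas3, Ntrk2, Dnase1, Traf2 and Tfpi2 had a retina mean over 15 at 1 site or both, near the highest normalized value of 15.59. The maximum of each array lay between 46528 and 53764 intensity units; whether these rows were saturated is not known, and saturation would make their differences too small. By the rule that chose them, in each of these 30 rows all 5 retina arrays lay on the same side of all 5 cortex arrays at both sites.

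By limma, 2413 of 9248 rows were called over both sites, 1143 higher and 1270 lower in retina, and 832 of them differed by at least 2 on the log2 scale. At the first site 2286 rows were called, 1099 higher and 1187 lower, and at site 2 there were 2560, of which 1231 were higher and 1329 lower. The retina and cortex arrays did not overlap in 36.3% of rows at the first site and 36.6% at site 2, where chance gives 0.794%. With the 3 first-site arrays that had 791 to 811 rows at 0 as a block, 2264 rows were called at the first site; within these, 2 retina arrays against 1 cortex array gave 2028 calls, under the assumption that the lone cortex array varied like the other groups, and the other 7 arrays gave 2222. Without normalization between arrays the split over both sites became 704 higher and 1980 lower, and that at site 2 became 417 higher and 3275 lower, where the medians of all rows lay at -0.33 and -0.69 on the log2 scale.

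Rows that separated retina from cortex at 1 site largely did so at the other. For instance, the row listed as Pcp2 differed by 8.56 at the first site and 8.84 at site 2, and the row listed as Anapc11 by -7.27 and -7.75. The rule for the 30 rows required a call in the same direction at both sites, so these examples are not separate evidence. Of the 30 rows above, 3 were called in the interaction, that is, differed between the sites: those listed as Tnni1 (10.66 and 9.24), Ntrk2 (9.47 and 7.88) and Cdh23 (-4.87 and -6.28). Across all rows the 2 sets of log2 differences, which share no arrays, correlated with r = 0.885 and rho = 0.783, and 95.9% of the 3010 rows called at either site had the same sign at both. Rows called higher in retina at both sites numbered 879 against 146 expected from independent lists, and rows called lower at both numbered 956 against 171. Both lists came from 1 fit with a shared spread per row after joint normalization, so they were not independent by construction. There were 450 rows called only at the first site and 724 only at site 2, and 1 row was called in opposite directions. The orthogonal slope of the site 2 differences against those of the first site, which treats both sites alike, was 1.02 over the rows called at either site.

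**Figure D3:**
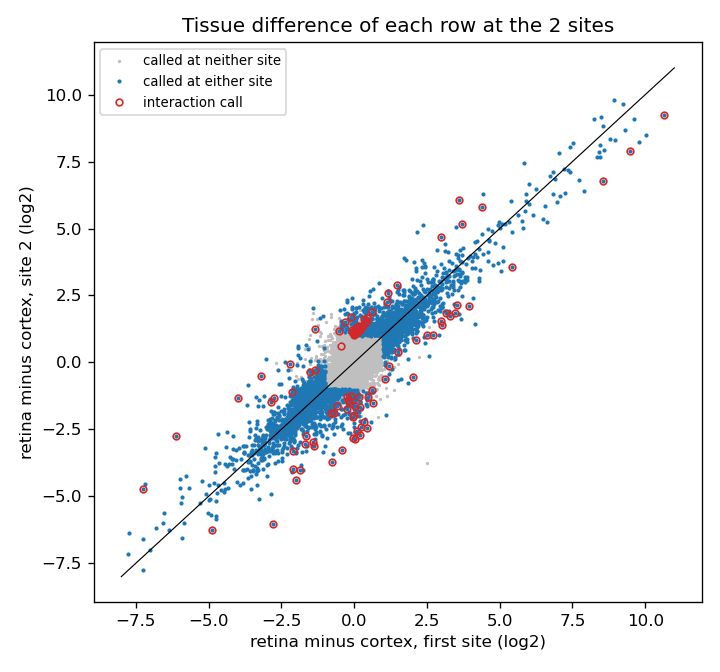
Retina minus cortex (log2) of each row at the first site (horizontal) and at site 2 (vertical); grey points were called at neither site, blue points at either site, red circles mark the 94 interaction calls, and the line marks equal differences. The points lie along the line, with r = 0.885 over all rows.

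None of the 29 gene lists fixed beforehand stood apart from the other rows by limma's camera test, where 2 had an unadjusted p under 0.05. The lowest adjusted p was 0.0637, for the oligodendrocyte and myelin list, whose 13 rows included 5 called lower and 0 called higher in retina with a median difference of -0.62; with an estimated correlation its adjusted p was 0.148. Its largest differences were in the rows listed as Olig1 (-3.36), Pdgfra (-2.86), Mog (-1.81) and Sox10 (-1.52). The lens list had an unadjusted p of 0.0259 and an adjusted p of 0.375, with 3 of 18 rows called higher and 0 lower. The test fry, which asks only whether a list's rows move on balance 1 way, passed 20 lists, and its mixed form passed all 29. The median, the mean and the camera direction differed in sign for 12 lists.

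Among the rows listed under rod photoreceptor genes 2 of 29 were called higher and 5 lower in retina; Tulp1 (3.79) and Rgs9 (3.42) were listed for rows that were higher, and Abca4 (-3.42) and Aipl1 (-1.97) for rows that were lower. Of the 10 cone photoreceptor rows 3 were higher, listed as Pde6c (5.52), Arr3 (2.20) and Thrb (1.03, a call that ended at 0.60 without normalization between arrays), and 1 was lower, listed as Rxrg (-3.38). The bipolar cell list had 1 row higher and 4 lower of 12, the amacrine, horizontal and ganglion cell list 1 higher and 0 lower of 18, and the Mueller glia list 0 higher and 1 lower of 15. The pigment epithelium list had 3 higher and 3 lower of 16. The immature neuron list had 4 higher and 5 lower of 31, and its 4 largest differences were in rows listed as Dcx (-6.31), Tmsb10 (-5.06), L1cam (-2.10) and Marcksl1 (-2.07). The list of cortical projection neuron transcription factors had 4 higher and 4 lower of 28, the interneuron list 2 and 2 of 16, and the radial glia list 5 and 3 of 24. The cell cycle list had 9 higher and 10 lower of 51, the axon guidance list 6 and 8 of 37, and the synaptic list 6 and 2 of 38. The astrocyte list had 1 higher and 2 lower of 14, the microglia list 3 and 4 of 23, and the endothelial list 1 and 2 of 24. The collagen and meninges list had 10 higher and 6 lower of 36, the erythroid list 3 and 4 of 16, and the muscle list 3 and 2 of 25. The imprinted gene list had 2 higher and 2 lower of 23, the glycolysis list 2 and 2 of 19, and the oxidative phosphorylation list 4 and 3 of 33.

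The cytosolic ribosome list had 4 higher and 6 lower of 42, led by rows listed as Rps20 (-6.92), Rpl22 (2.96), Rps3 (2.64) and Rpl24 (-2.60). The splicing and chromatin list had 4 higher and 7 lower of 37, the immediate early and heat shock list 7 and 2 of 32, and the list of class I antigen presentation and interferon response 7 and 2 of 18. Of all 7773 genes with a row, 12.4% were called higher and 13.5% lower. Adjusted over the list alone, the counts were equal except for the Mueller glia list, with 2 rows, and the astrocyte list, with 4. Among the 11 rows listed under housekeeping genes, commonly used as references, those listed as Tfrc (8.13), Hprt (5.02) and B2m (1.80) were called higher in retina and those listed as Polr2a (-1.16) and Pgam1 (-1.15) lower. The others, listed as Rplp0 (-0.80), Tbp (0.45), Ppia (-0.36), Gusb (-0.33), Pgk1 (0.23) and Eef1a1 (-0.13), were not called, and the difference of the row listed as Pgk1 turned to -0.12 without normalization between arrays.

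The tissue difference itself changed between the sites in 94 rows. In the row listed as Chaf1a the retina minus cortex difference was -1.35 at the first site and 1.25 at site 2, an interaction of 2.60 ± 0.17 (SE) with an adjusted p of 1.11e-07. Interactions in the rows listed as Slc2a2, Hand2, Krtap12-1 and Atr were 2.46, 2.15, 1.84 and 1.71. In the other direction, the row listed as Ropn1 had an interaction of -3.23 ± 0.47 (SE), with differences of -2.79 at the first site and -6.03 at site 2. Those of the rows listed as Slc22a13, Il25, Pglyrp2 and Mpp3 were -2.93, -2.40, -1.89 and -1.89. With the higher floor the interactions of the rows listed as Ropn1 and Il25 became -0.74 and -0.53 and were no longer called. The call of the row listed as Il25 was also lost when any 1 of 17 of the 20 arrays was left out, with values of -2.53 to -2.06. Of the 94 rows, 41 had a higher and 53 a lower retina minus cortex difference at site 2. That split was 94 against 56 with median scaling, 75 against 83 with normalization within each site, and 16 against 2150 without normalization, where the median of all rows lay at -0.81; with the 3 first-site arrays that had more rows at 0 as a block, 102 rows were called. At an adjusted p under 0.01 it was 27 against 17 of 44 rows, and without these 3 arrays 32 against 28 of 60, so the direction of the split was not stable.

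The same pool gave different values at the 2 sites in part of the rows. In retina the row listed as Cdh22 was higher at site 2 by 7.85 ± 0.66 (SE), and those listed as Itga6, Mobp, Ss18 and Elk3 by 4.12, 3.30, 2.63 and 2.42. Lower at site 2 in retina was the row listed as Gem, by -7.57 ± 0.47, and those listed as Pglyrp1, Magi1, Magea2 and Sprr1a had differences of -5.93, -5.67, -3.88 and -3.73, with an SE of 1.68 for the row listed as Pglyrp1. That row had an SD of 5.61 between the 5 retina arrays of site 2, against 0.10 between those of the first site, so the site 2 arrays did not share 1 level. In cortex the row listed as Slc34a1 was higher at site 2 by 5.74 ± 0.54, and those listed as Cdh22, Slc22a13, Mobp and Elk3 by 5.34, 2.41, 2.37 and 2.19. In cortex the difference of the row listed as Gem was -8.54 ± 0.47, and those listed as Magea2, Adam9, Magi1 and Amy1 had -3.39, -3.39, -3.36 and -3.34. With the higher floor the differences of the rows listed as Cdh22 and Gem became 4.97 and -5.55 in retina and 2.78 and -5.79 in cortex, and that of the row listed as Slc34a1 became 3.15. All stayed called, but their sizes depend on the floor. There were 1514 calls in retina, 691 higher and 823 lower at site 2, and 1015 in cortex, 408 higher and 607 lower. With median scaling the splits became 1280 against 630 and 843 against 532, where the medians of all rows lay at 0.18 and 0.11, and with the 3 first-site arrays that had more rows at 0 as a block there were 1302 and 1016 calls. Without normalization between arrays 6658 of 6677 calls in retina and 3521 of 3569 in cortex were lower at site 2, with medians of all rows at -1.60 and -0.78, and with normalization within each site 4914 of 5003 and 4891 of 4942 were, with medians at -1.11 and -1.10.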

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

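Except for the background level, the normalizations and the other splits of the arrays, the tests were chosen only after the results were seen: those of the row names, of the signal level and the compression of differences, of swapped labels, and of the splits with the tissue and site effects removed.

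In general the names of the rows did not match the values, and this was weighed first. Copy 32 of 2 control series was an exception, described under the other observations. Poor measurement is argued against by the correlation of row means of 1 pool between the sites, which was at least 0.962. Wrong gene symbols alone are argued against by the copies of repeated controls, whose identifiers need no symbol and whose median SD was 1.14 times that of all rows. A candidate explanation is that the names were displaced along the array. Rows listed with the same copy number of different controls shared their deviations between replicate arrays, with a mean r of 0.274. It was at most 0.225 when the copy numbers were shuffled within each name (permutation p = 1e-05, the smallest the permutations can give). Over all pairs of control rows it was 0.195. Levels also differed by copy number (permutation p = 1e-04). Rows close together could share deviations under correct names too, so the test of deviations does not separate displaced from correct names. No biological explanation was tested, since it would not apply to copies of a control.

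The tissue by site interaction called 94 rows, although both sites received RNA of the same pools. Lower signal at site 2 as the whole cause was tested by the level of these rows. Of the 94, 51.1% lay above the median level (exact 95% interval 40.5% to 61.5%). This cannot decide it, because dim rows varied more at site 2, with an SD of 1.07 in retina and 1.06 in cortex in the lowest quartile. Calls are harder to reach there, and the level was a mean over both sites. With the higher floor 131 rows were called, 73 of the 94 among them. Without dim rows 97 were called, 76 of the 94 among them. The count thus did not fall, but part of the 94 rows was lost and others were called, so lower signal stays open. Compressed differences at 1 site stay open: 65 of the 94 rows had the larger difference at site 2 and 29 at the first site, and dividing the site 2 differences by the slope of 1.02, which kept 95.7% of the calls, changed too little to test it. The normalization between arrays stays open too: between 57.4% and 86.2% of the 94 rows were kept under the other normalizations, between the bounds set beforehand. No biological explanation was tested, because the design offers none.

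On the 3 first-site arrays with more rows at 0, retina replicates 4 and 5 and cortex replicate 3, deviations from the group means correlated with each other with a mean r of 0.463. A different background level would act on dim rows. As the only cause of these shared deviations it is argued against by the brightest quartile of rows, where the mean r was 0.465. In the lowest quartile it was 0.470, so a background difference beside another shared effect stays open. The test does not address the rows at 0 themselves. On all 3 arrays 592 rows were at 0, and their median was 0.255 intensity units on the other first-site arrays. Swapped tissue labels are argued against by the correlation of each array with its own group, which exceeded that with the other tissue by at least 0.0629. A shared hybridisation or scanning batch stays open and was not tested, as the labels name none. No biological explanation was tested, since all arrays of a tissue carry 1 pool.

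Single arrays stood far from the other 4 of their group in 2 of 16 array-level comparisons and in 11 of 120 groups of the named rows, where chance gives about 1 in 20, that is 0.8 and 6. Cortex replicate 3 of the first site had 811 rows at 0 against 267 to 398, and its mean r with its group was 0.964 against 0.976 to 0.981. On that array the row listed as Acrv1 was at 1.52 (log2), the floor, against 4.08 to 5.09, the row listed as Pcdhb15 at 14.79 against 14.43 to 14.53, and the row listed as Ngly1 at 4.82 against 6.87 to 7.26. Gabpb1 was the name of a row at 15.03 on retina replicate 3 of the first site against 14.52 to 14.67, and at 7.60 on cortex replicate 4 of site 2 against 4.75 to 5.34. On that same site 2 array the row listed as Mthfs was at 9.59 against 10.17 to 10.29. On cortex replicate 2 of the first site the row listed as Rps20 was at 11.81 against 12.07 to 12.15. At site 2, the row listed as Snx4 was at 12.84 on retina replicate 3 against 13.09 to 13.17, and the row listed as Ntrk2 at 15.43 on retina replicate 2 against 15.48 to 15.50. There, too, the row listed as Tra2b was at 1.52 on cortex replicate 5 against 4.63 to 5.23, and the row listed as Tfrc at 2.19 on cortex replicate 2 against 4.35 to 5.11.

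The tissue difference differed between the sites by limma's interaction test in the row listed as Chaf1a by 2.60 (adjusted p = 1.11e-07), Slc2a2 by 2.46 (0.000916), Hand2 by 2.15 (0.00127), Krtap12-1 by 1.84 (0.000368) and Atr by 1.71 (0.0128). It differed in the row listed as Ropn1 by -3.23 (0.000686), Slc22a13 by -2.93 (7.17e-06), Il25 by -2.40 (0.0486), Pglyrp2 by -1.89 (0.00014) and Mpp3 by -1.89 (0.000368). With the higher floor the interactions of the rows listed as Ropn1 and Il25 shrank to -0.74 and -0.53 and were not called. That of the row listed as Il25 was lost, too, when any 1 array was left out except retina replicate 3 of the first site and retina replicates 1 and 4 of site 2.

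The counts of calls were set against 100 splits of the arrays, the real one included, so 1 in 100 is the smallest share they can give. For retina against cortex and between the sites the real split alone reached its count. At that level this argues against groups of arrays without any real difference. The other splits mix the groups, which adds a real difference to the spread and lowers their counts. Their counts therefore say nothing about the number of false calls. For retina against cortex, 1 of the 100 splits, the real one, gave as many calls at the first site (2286, highest other 965), at site 2 (2560, highest other 859) and over both sites (2413, highest other 1173). Between the sites the real split alone, 1 of 100, gave 1514 calls in retina and 1015 in cortex, with 324 and 34 as the highest others. For the interaction 2 of the 100 splits gave 94 calls or more, and the other such split gave 2288; these splits carry the tissue difference into the contrast or into the spread, a structure of the arrays, and decide nothing about chance. With the tissue and site effects of each row removed before the tissue labels were shuffled within each site, 1 of 100 splits, the real one, gave 94 calls, and the highest other gave 2. These splits leave the 3 first-site arrays with more rows at 0 in place; 60 rows were called without them and 102 with them as a block.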

How the results depend on the processing

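The omission of control rows and every setting with the 3 first-site arrays that had more rows at 0 were chosen after the data were seen. Calling by adjusted p without a fold minimum gave 4034 rows at the first site, 4330 at site 2, 4965 over both sites, 193 for the interaction, and 3496 and 2649 between sites in retina and cortex. The 3 counts for retina against cortex stayed within 1.5 times under every other setting run. The 94 interaction calls became 150 with median scaling, 2166 without normalization, 158 with normalization within each site, 44 at an adjusted p under 0.01 and 60 without the 3 first-site arrays, which also leaves fewer arrays; with these as a block it was 102, of which 85 were among the 94. The count thus depends on the scaling, and the cause was not tested. Between sites, 6677 rows in retina and 3569 in cortex were called without normalization and 5003 and 4942 with normalization within each site, both of which leave the dimmer signal of site 2 in the contrast by construction. The median SD rose without normalization to 0.53 in retina and 0.56 in cortex at site 2; it fell to 0.25 and 0.24 without dim rows, to 0.25 and 0.23 with the higher floor, and to 0.22 with that floor in cortex at the first site. The correlation between sites was 0.917 with median scaling, 0.944 without dim rows and 0.935 with the higher floor. The cause was not tested. The SD in the lowest quartile of levels, 1.07 in retina and 1.06 in cortex at site 2, limits the precision of dim rows.

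With each array left out in turn, calls ranged from 2214 to 2372 at the first site, 2510 to 2640 at site 2, 2363 to 2475 over both sites, 74 to 108 for the interaction, 1341 to 1561 between sites in retina and 953 to 1069 in cortex. The median SD ranged from 0.27 to 0.32 and 0.24 to 0.29 for retina and cortex at the first site and from 0.29 to 0.34 and 0.25 to 0.33 at site 2, and the correlation between sites from 0.873 to 0.894. In each setting run for the gene lists 0 were called by camera, with the smallest adjusted p at 0.0518 without cortex replicate 5 of the first site and 0.0532 with the 3 arrays as a block. Of 60 named results 50 kept their call under every setting that gave a value, 10 lost it under at least 1, most often without normalization between arrays (7), and 0 reversed. Of 114 list members 97 kept theirs under every setting, 13 lost it and 3 gained one under at least 1, and 1, the row listed as Pgk1, reversed from 0.23 to -0.12 without normalization. The interaction of the row listed as Il25 was no longer called when any 1 array was left out, except retina replicate 3 of the first site and retina replicates 1 and 4 of site 2 (-2.53 to -2.06 where the call was lost). The row listed as Thrb fell under the fold minimum of 1 without retina replicate 2, cortex replicate 1 or cortex replicate 3 of site 2 (0.98 to 1.00).

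The replicate numbers did not pair the arrays: 1 of 10 same-numbered pairs of retina and cortex had deviations correlating over 0.1 (range -0.43 to 0.15), and 0 arrays were closest to their own number. With the replicate block, calls were 2255, 2525 and 2395 for retina against cortex at the first site, site 2 and both, 40 for the interaction (21 higher and 19 lower), and 1515 and 1018 between sites in retina and cortex, with 0 lists called.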

Other observations

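The comparisons of numbered rows and control copies were chosen after their values were seen. In 2 runs of 6 rows with consecutive numbers, 54 to 59 and 187 to 192, levels rose in steps, and the runs matched each other with a root mean square difference of 0.505 on the log2 scale, against at least 1.15 in 1000 shuffles of the numbers. Rows listed as copy 32 of 2 repeated control series lay 0.581 from the first run, and rows listed as the other copies at least 5.52. In the first run the rows numbered 54, 56 and 58 had retina minus cortex differences over both sites of -0.36, -0.53 and -0.52, and those numbered 55, 57 and 59 had 1.65, 1.28 and 0.79 (limma). In the second run the rows numbered 187, 189 and 191 had -0.61, -0.80 and -0.84, and those numbered 188, 190 and 192 had 1.35, 0.92 and 0.53. The rows listed as copy 32 in that comparison had -0.48, -0.78 and -0.58 for the first control series. They had 1.32, 1.13 and 1.11 for the second. The remaining copy 32 rows of these series had -0.21 in the first and 1.85 and 1.73 in the second. Ordered from the largest number after the series name to none, mean levels of copy 32 rose in both series. They were 10.25, 12.47, 13.69 and 14.34 in the first and 8.15, 10.25, 12.61, 13.70 and 14.25 in the second. These levels followed the listed names, so the names of these rows may be right. The row after each run, numbered 60 and 193, had a mean level of 1.68 and 1.67 on the log2 scale, near the floor of 1.52. Rows listed as numbered or repeated control spots were at 0 on more than 60% of the arrays in 13.1% of cases, against 0.955% of the other rows.

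Of the 94 interaction calls, 77 were also called between the sites in retina or cortex, 22 had tissue differences of opposite sign at the 2 sites, and 65 had the larger difference at site 2.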
